A study of Eucalyptus grandis with 4 samples.

How the data were processed

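RNA of Eucalyptus grandis cuttings was measured on 4 2-colour arrays, each with RNA of juvenile cuttings in 1 channel and of mature cuttings in the other. The groups, dyes and replicate numbers were taken from the sample titles and the labels of each channel. Mature RNA was in Cy5 on 2 arrays (replicates 1 and 2) and in Cy3 on the 2 dye-swapped arrays. The labels call the 2 replicates per stage biological.

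The deposited scanner files hold spot intensity on a linear scale, the mean and median of each spot and of its local background in each channel, extracted with Agilent Feature Extraction 10.5.1.1, per the file headers. They also hold the program's own ratio of Cy5 over Cy3, a log10 value after its spatial detrending and dye normalization, per the file headers. The submitters' processing notes name limma, and how they used it is not given in the sources used here. The authors' deposited table of log ratios was not used, because its 45220 rows cycle through 4 distinct values (45216 rows equal the value 4 rows before), so it holds no value per probe. Its log base is not stated, and its comment line speaks of roots, where the labels of all 4 arrays give cuttings as the tissue. The labels were followed.

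Each array had 45220 spots, of which 43803 were plant probes, each spotted once, and 1417 were controls. Median Cy5 signals were 930, 1296, 1340 and 1251 and median Cy3 signals 798, 955, 514 and 591, over median backgrounds of 42 to 44 in Cy5 and 31 in Cy3. These values are in the order mature in Cy5 replicates 1 and 2, then juvenile in Cy5 replicates 1 and 2. All 4 arrays were on 1 slide and in 1 scan, so no batch could be tested.

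In R 4.3.3 with limma 3.58.1, mean signals were corrected with normexp (offset 50, fitted on all spots) and normalized by loess within each array with control spots at weight 0, without scaling between arrays. Spots marked as non-uniform or population outliers (11 to 24 per array) were left out. Probes were kept when well above background in at least 1 channel on at least 2 arrays, which dropped 1336. Every log2 ratio was turned to mature over juvenile. The 2 arrays of a replicate carry the same stage and replicate labels, were taken as technical repeats of the same 2 RNA extracts and were averaged, though the consensus correlation of their log2 ratios was -0.17. Whether the extracts were the same was not settled by the data. The 2 replicate values were tested against 0 with lmFit and eBayes (1 residual degree of freedom plus 5.28 from the variance prior), with Benjamini-Hochberg adjustment at 0.05. Mature and juvenile RNA of the same replicate number share an array, so the replicate is a block by construction. As a check of this pairing, the deviations of the arrays with mature RNA in Cy5 and of the dye-swapped arrays from their means correlated across probes with r = 0.07 between arrays of the same number. This r is low and lends the pairing little support, so the p-values may not measure the spread between biological replicates. The dye effect was fitted on the 4 arrays with a ratio for each replicate and a dye coefficient.

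The test was run on simulated data (42465 probes), with independent probes and variances drawn from the prior fitted to the real probes. With 50 probes changed at each size, it recovered 2% at 1.5-fold, 26% at 2-fold, 96% at 3-fold and 98% at 4-fold, and called 7 unchanged probes among 118 calls. With 2474 probes changed 2-fold, it recovered 96.4% and called 175 unchanged probes among 2561 calls. The simulated values follow the model of the test, so these shares of false calls do not check the real calls. Correlation between the probes of a contig and the unequal spread of the real arrays were not simulated.

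A contig is the probe name without its base positions. Probes that name no gene were reported at most 2 per direction, the largest mean log2 ratios among probes past the threshold with the same sign on all 4 arrays, each contig through its probe with the highest mean signal. The files describe every plant probe as unknown, and none of the probes matched the reference table of 42619 genes (assembly ASM1654582v1), so the planned results for nitrate reductase and for the 28 gene lists were not computed. No genome was used here, and the strand of the contigs and the full contig sequences were not used.

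Single-channel log2 values came from loess followed by quantile scaling of mean signals between arrays. The distance between channels was taken from the covariance between the 2 probes of each contig with a mean log2 signal above 8, which leaves out noise of single spots. The spike-in offset of a replicate is the mean over its 2 dye orientations of each spike's log2 ratio, which cancels the ratio at which a spike was mixed. Probes of contigs in 1 cluster were aligned with blastn 2.17.0. For the counts of probes, alternatives for background, signal, normalization, dim probes, flagged spots, arrays left out, technical repeats, pairing and the variance prior were fixed before the data were examined. Centring on spike-in controls, per replicate or by their mean, averaging the probes of a contig and every alternative for the dye effect were added after seeing the data.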

Results

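Mature and juvenile RNA of Eucalyptus grandis, from cuttings per the labels, was compared on 2-colour oligonucleotide arrays. Seedlings 6 to 7 months old had been pruned either at 10 to 15 cm or at 150 to 200 cm above the ground, and the shoots that grew afterwards were taken as cuttings. Per the labels, cuttings from the low-pruned seedlings, called juvenile, rooted in 45% of cases after 14 days and in 60% after 35 days following a dip of 20 seconds in the auxin K-IBA at 6000 ppm. Cuttings from the high-pruned seedlings, called mature, rooted in 5% of cases after 35 days. The labels do not say whether the RNA was taken before or after the auxin. RNA of 2 biological replicates per stage was hybridised on 4 arrays, with mature RNA in Cy5 on 2 of them and the dyes swapped on the other 2. Each array held 43803 plant probes from 24220 assembled contigs, and 18473 contigs had 2 or more probes. Between 93.3% and 96.4% of the probes lay well above background in Cy3, and between 95.7% and 96.7% in Cy5. No plant probe was saturated on any array. With 2 replicates per stage, the number of replicates limits the precision.

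The files describe each probe as unknown and do not pair probes with genes, so the results are given for probes and contigs, and no gene is named. The series' title names nitrate reductase, the enzyme that reduces nitrate to nitrite in plants. Its probes could not be picked out, and the 28 gene lists fixed beforehand matched no probe.

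The comparison asked which transcripts differed between cuttings that rooted readily and cuttings that barely rooted. The probe with the largest rise in mature cuttings under the naming rule belonged to contig22031. On this probe (contig22031_length=239_numReads=2_51-110, sequence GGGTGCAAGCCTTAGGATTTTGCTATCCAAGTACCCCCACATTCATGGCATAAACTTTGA, bases 51 to 110 of the contig) the log2 ratio of mature over juvenile was 3.83 ± 0.68 (SD, n = 2), a 14.2-fold higher signal, with an adjusted p of 0.0025 in limma. Its second probe on the same contig gave 4.66 (adjusted p = 0.0025). Contig KIRST.5239.C1 followed, with 3.62 ± 0.70 (SD, n = 2) on its brighter probe KIRST.5239.C1_nseq=17_596-651 (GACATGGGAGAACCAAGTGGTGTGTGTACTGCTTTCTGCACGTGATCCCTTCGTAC), or 12.3-fold, and 2.86 on its other probe. The adjusted p was 0.00262 on both probes.

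In the other direction, contig KIRST.16167.C1 had the largest difference under the same rule. Its probe KIRST.16167.C1_nseq=4_37-92 (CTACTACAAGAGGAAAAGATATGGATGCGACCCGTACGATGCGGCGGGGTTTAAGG) had a log2 ratio of -3.42 ± 0.72 (SD, n = 2), which is 10.7-fold higher in juvenile cuttings (limma adjusted p = 0.00304). It was the contig's 1 tested probe. Contig KIRST.21023.C1 had -3.18 ± 0.63 (SD, n = 2) on its brighter probe KIRST.21023.C1_nseq=5_120-175 (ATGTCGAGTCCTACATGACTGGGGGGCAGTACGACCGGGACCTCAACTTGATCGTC), or 9.06-fold (adjusted p = 0.00297), and -3.30 on its other probe (adjusted p = 0.00316). All 4 of these contigs were well above background in the 4 mature and the 4 juvenile channels. The naming rule required the same sign on all 4 arrays. Without the replicate 1 array that had mature RNA in Cy5, their log2 ratios were 3.31, 3.23, -3.75 and -3.43 in the order given, and none passed the limma test (adjusted p from 0.145 to 0.158). The dye-swapped array of replicate 1 gave the smallest rise for both contigs that were higher in mature cuttings, 2.32 and 2.35, and the largest difference for both that were higher in juvenile cuttings, -4.59 and -4.13.

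**Figure D1:**
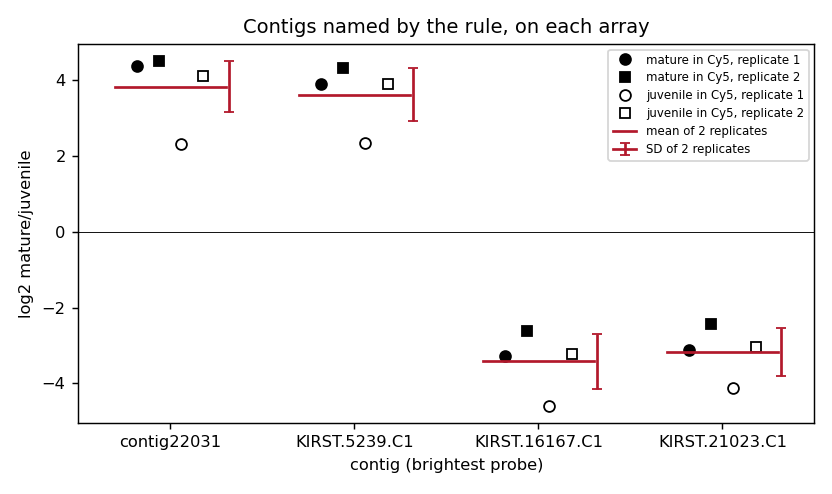
Log2 ratio of mature over juvenile signal (vertical axis) for the 4 named contigs (horizontal axis), through each contig's brightest probe. Filled symbols are arrays with mature RNA in Cy5, open symbols are dye-swapped arrays, circles are replicate 1 and squares replicate 2, and the red line and bar give the mean and SD of the 2 replicates. The contigs were chosen among those with the same sign on the 4 arrays, and the dye-swapped array of replicate 1 is the lowest point for all 4.

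Of 42465 probes tested, 2474 (5.83%) differed between the stages at a Benjamini-Hochberg adjusted p below 0.05 in limma. Of these, 947 were higher in mature cuttings and 1527, or 61.7%, in juvenile cuttings. An unadjusted p below 0.05 was reached by 9494 probes. Of the 2474 called probes, 2268 had the same sign on all 4 arrays. The others changed sign between arrays or lacked a value on an array. The 2 dye orientations of a replicate were averaged before the fit, so disagreement between them did not enter its residual variance. The median change was 1.86-fold among the probes higher in mature cuttings and 1.91-fold among those higher in juvenile cuttings. Counting each contig once through its brightest probe, 1412 contigs differed, 532 higher in mature and 880 higher in juvenile cuttings. This split is relative to the centre of all probes on each array. Relative to the 10 spike-in controls, a centring chosen after seeing the data, the median probe lay 0.38 higher in mature cuttings on the log2 scale, and 8888 probes were called higher in mature against 799 in juvenile cuttings. The numbers of these calls are not comparable with 2474, because the offset differed between the replicates and its spread, added to every probe, changed the variance prior (infinite prior degrees of freedom, against 5.28). With the mean offset taken from both replicates, as if it had no error, the prior was as before and the split was 19777 against 1093. The count also rested on single arrays. It was 0 in limma without the replicate 1 array that had mature RNA in Cy5 (4695 probes at an unadjusted p below 0.05), and 1267 without the dye-swapped array of replicate 2. Without the dye-swapped array of replicate 1, which had the widest ratios, it was 3458. A fit without the replicate block, which does not use the pairing of the RNAs on an array, called 1601 probes.

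**Figure D2:**
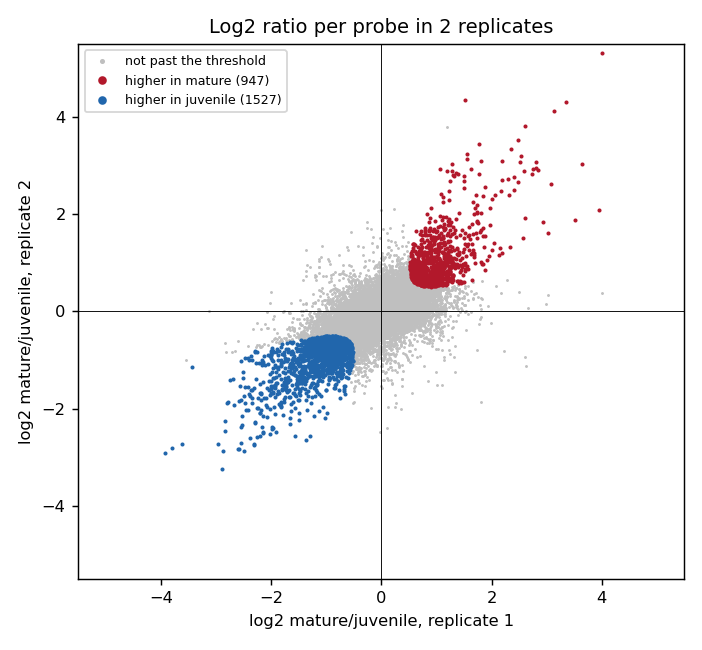
Log2 ratio of mature over juvenile signal per probe in replicate 1 (horizontal axis) and replicate 2 (vertical axis), each the mean of 2 dye orientations. Red points are the 947 probes higher in mature and blue points the 1527 higher in juvenile cuttings at an adjusted p below 0.05 in limma. Every one of them has the same sign in both replicates, which a call in this test required, so it is not separate evidence of agreement. On the 4 single arrays, 2268 of them have the same sign throughout.

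By size and direction alone, 1006 probes differed at least 2-fold with the same sign on all 4 arrays, 352 higher in mature and 654 higher in juvenile cuttings. The count was 1819 (664 and 1155) with the scanner's own log ratio, and 1757 without replicate 2, where only 2 signs had to match. Of the 1006 probes, 946 also passed the limma test. At 4-fold or more there were 45 probes higher in mature and 63 higher in juvenile cuttings. Over all probes kept, 35.6% had the same sign on the 4 arrays, where 4 unrelated signs would give 12.5%. That is not the share for no difference between the stages if the 2 arrays of a replicate carried the same extracts. Centred on the spike-in controls, 1226 probes were at least 2-fold higher in mature and 271 in juvenile cuttings. The 2 replicates' log2 ratios correlated across probes with r = 0.64 (Spearman 0.54), and probes are not independent replicates.

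Different probes of a contig gave like values. Across the 16569 contigs with 2 tested probes, the log2 ratios of the 2 probes correlated with r = 0.91. Among 1294 contigs with 2 or more tested probes and at least 1 call, 810 had all their probes called in the same direction, and in 1266 all probes had the same sign. Probes called in opposite directions occurred in 2 contigs.

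No probe passed the threshold for a dye effect in limma (0 of 42409 probes measured on all 4 arrays), and 2653 had an unadjusted p below 0.05, where chance gives about 2120. The dye coefficient was at least 2-fold in size on 136 probes. Its SD over probes was 0.20 on the log2 scale, against 0.38 for mature over juvenile. This model has 1 residual degree of freedom, which limits what it can detect.

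The 4 arrays differed in how far they agreed. The log2 ratios of the 2 arrays with mature RNA in Cy5, which carry different replicates, correlated across probes with r = 0.71, and those of the 2 dye-swapped arrays with r = 0.39. The pairs that differ in both replicate and orientation had r = 0.37 and 0.51. The 2 arrays of replicate 1 correlated with r = 0.39 and the 2 arrays of replicate 2 with r = 0.55. Among the 8 channels, compared over 13002 contigs in a way that leaves out spot noise, the mature replicate 1 RNA in Cy3 lay 0.58 log2 units from the RNA labelled as the same extract in Cy5. The other 3 pairs of channels labelled as 1 extract lay 0.24, 0.24 and 0.37 apart. That channel was also the farthest from the 4 juvenile channels, at 0.62 to 0.68, where the other 3 mature channels lay 0.39 to 0.50 from them. The 2 mature channels in Cy5, of different replicates, lay 0.24 apart. Each was closer to the other than to its own labelled extract in Cy3 (0.58 and 0.37). The 2 mature channels in Cy3 lay 0.57 apart.

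**Figure D3:**
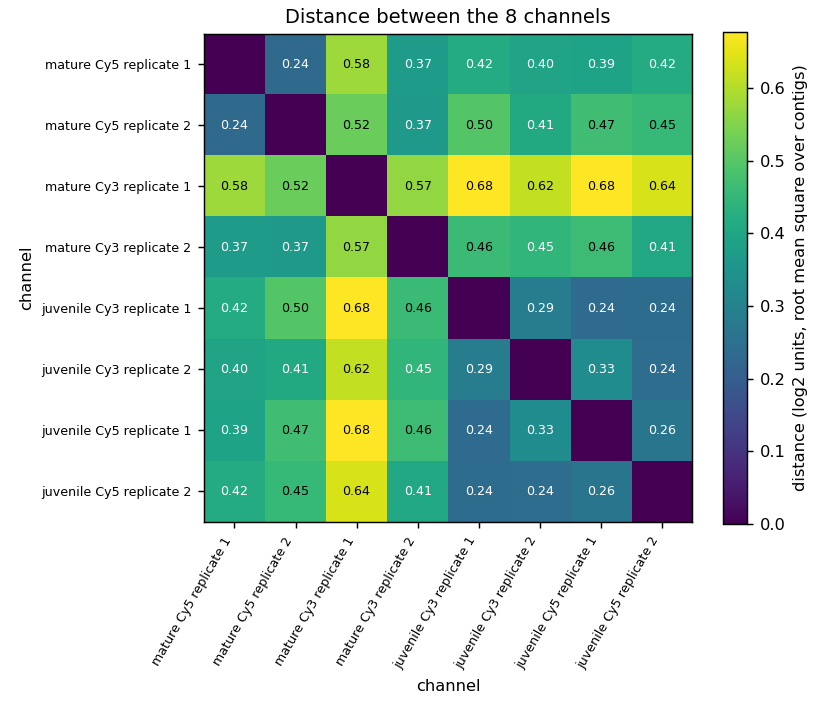
Distance between each pair of the 8 channels in log2 units, as the root mean square over 13002 contigs after removal of spot noise. Rows and columns are the channels by stage, dye and replicate, and lighter cells are larger distances. The mature Cy3 replicate 1 channel lies 0.52 to 0.68 from every other channel, while the 4 juvenile channels lie 0.24 to 0.33 from each other.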

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

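Apart from the share of calls without the outlying array, the tests in this part were chosen only after the result was seen. The 4 arrays measure the same ratio, and 14 quantities were compared over them for an array far from the other 3. Chance flags about 1 in 20, or 0.7 here. The dye-swapped array of replicate 1 was far from the others on 3. The SD of its log2 ratios over probes was 0.67, against 0.42 to 0.43 on the others. Feature Extraction called 8112 probes higher in Cy5 and 8376 lower on it, against 3228 to 3768 and 3154 to 3795 on the others. These 3 quantities are not independent.

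Over the 8 channels, the mature RNA in Cy3 on this array was the farthest from the rest. Spot noise is argued against as the source of the wider ratios. The variance of the log2 ratio was 0.452 on this array and 0.175 to 0.189 on the others, and at most 9.17% of the excess lay in the part that the 2 probes of a contig did not share. Loss of part of the transcripts stays open. The downstream probe lay -0.067 ± 0.014 (SE, 523 contigs) from the upstream one. The largest shift in size, 0.13, was in the juvenile RNA in Cy5 on the same array, a channel that did not stand apart. These 2 shifts have opposite signs and so move this array's ratio the same way, and the 0.13 does not count against a loss. Neither the strand of the contigs nor the priming is given. Whether the channel held RNA other than the labelled extract stays open too, since its distance of 1.57 times the largest of the other 3 between channels of 1 extract restates the pattern, and no biological explanation was tested, because the labels put both channels in the same replicate of mature cuttings.

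A further pattern was that 61.7% of the called probes were higher in juvenile cuttings. Without the outlying array the share was 57.9%, lower but still more than an even split, so this array alone does not account for all of it. Replicate 1 then rested on a single dye orientation, so a dye effect could enter this share. The split also depends on where the ratios are centred. All 10 spike-in controls lay below 0 for mature over juvenile in both replicates, with means of -0.53 ± 0.19 (SD over 10 spikes) in replicate 1 and -0.24 ± 0.06 in replicate 2. Centred on them, 8.25% of the calls were higher in juvenile cuttings (5.24% with the mean offset of both replicates), which follows from the offset itself and does not show which centre is right, so centring as the source stays open. Whether the offset reflects the amount of messenger RNA in the cuttings or of spike added was not tested, and a difference between the stages stays open as well.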

How the results depend on the processing

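The alternatives were planned, except centring on the spike-in controls, averaging the probes of a contig and all those of the dye effect, which were chosen after seeing the data. The number of probes past the threshold stayed within 1.5 times 2474 under background, signal, normalization, filter, flag and variance prior alternatives (2074 to 3151). A like count did not always mean the same probes. Of the 2474 probes, 66.6% passed again with the scanner's own log ratio, and 87.1% or more under each of the others. The fit without the replicate block, which ignores the pairing, gave 1601, centring on the spike-in controls 9687 (20870 with the mean offset of both replicates), and averaged contigs 1285 (fewer units tested). Leaving out 1 array gave 0 to 3458: 0 without the array of replicate 1 with mature RNA in Cy5, and 1267 without the dye-swapped array of replicate 2. With the 4 arrays treated as independent it was 2036, and with duplicateCorrelation, whose consensus correlation was -0.17, 3585. A negative correlation makes the standard error of the mean smaller than independence does, so 3585 is not a cautious count. The share of the 2474 probes that passed again was 65.0% with independent arrays and 82.7% with duplicateCorrelation. It was 64.6% without the replicate block and 0% to 85.3% with 1 array left out. The count of probes at least 2-fold in the same direction (1006) rose to 1819 with the scanner's own log ratio and fell to 522 with averaged contigs. Leaving out arrays or replicates gave 1039 to 1757, over fewer signs that had to match. Apart from fewer units or arrays, the cause was not tested. Scaling between arrays (Aquantile) moves no ratio and is not counted below. The dye effect had 0 probes past the threshold in limma under its 8 other alternatives, with 2456 to 6416 at an unadjusted p below 0.05. The naming rule required the same sign on all 4 arrays, so leaving out or reweighting arrays could not reverse a named probe. The 4 named probes kept their direction in 19 alternatives and passed in 18. The exception was the fit that left no call, where they kept log2 ratios of 3.31, 3.23, -3.75 and -3.43 with adjusted p of 0.145 to 0.158 and replicate 1 rested on its dye-swapped array alone. Not run: the deposited table of log ratios (no value per probe), nitrate reductase and the gene lists (no annotation), and tests without a replicate pair (no residual degrees of freedom). Signal over background kept 1336 dim probes out of the reported test. With them included, 2203 probes passed, all among the 2474, so no dim probe was called.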

Other observations

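The tests in this part were chosen after the result was seen, except that of aligned probes in a cluster. Of the 43803 probes, 40311 were well above background in all 8 channels and 978 in none. In all 4 juvenile channels and no mature channel there were 53 probes, and in all 4 mature and no juvenile channel 4. The Cy3 signal was lower on the arrays where Cy3 held mature RNA (median 514 and 591) than where it held juvenile RNA (798 and 955), so these counts are open to that difference.

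The nseq value in a probe name was read as the number of sequences assembled into the contig. Contigs with more sequences had brighter probes (Spearman 0.50 across 18380 contigs). Of the contigs called, 56.8% were higher in juvenile cuttings among those of 2 sequences, 62.9% at 3 to 5, 67.0% at 6 to 20 and 80.3% of 71 at 21 to 100. Among 15 called contigs with over 100 sequences it was 46.7%. Over all 18380 contigs, called or not, the number of sequences and the log2 ratio had a Spearman correlation of -0.05. The shares are relative to the centre of all probes and their trend was not tested.

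Contigs that share a cluster number in the probe names were compared as unnamed groups (50 clusters of 5 or more contigs, 387 contigs). The mean variance of the log2 ratio within a cluster was 0.15, below that of each of 1000 shuffles of the contigs (mean 0.226, lowest 0.16). In limma's camera with a preset correlation, 6 clusters passed, 4 higher in mature and 2 in juvenile cuttings, and 0 passed with an estimated correlation. Probes that read the same sequence may account for part of the lower variance, though few pairs within clusters aligned. Aligned pairs (47) had 0.339 times the mean squared difference of pairs from different clusters. Pairs that did not align (1857) had 0.874 times (95% bootstrap interval 0.526 to 1.25). That interval spans no difference, so the part beyond shared sequence cannot be told apart from none. These ratios weigh each pair alike, so large clusters count more in them than in the mean variance within a cluster.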
